A study of Danio rerio with 10 samples.

How the data were processed

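RNA was sequenced from zebrafish testis tissue, 5 control libraries (11KT alone) and 5 Amh libraries (11KT and Amh), each from tissue kept 3 days in culture. Per the labels, RNA was isolated with a miRNeasy kit and libraries were made from 2 µg of total RNA with an Illumina TruSeq kit. The deposited values are counts, raw read counts per Ensembl gene as whole numbers, with no normalization, 1 file per library. The submitters' processing notes name FastQC 0.10.1, TopHat2 2.0.5, SAMtools 0.1.18, HTSeq, DESeq and the genome build Zv9, without saying which made the counts. The annotation release, the counting mode and the strand setting are not given in the sources used here, so reads shared between paralogues may count for either gene or for neither.

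The tables held 33737 genes, of which 29017 had at least 1 read and 21939 had a symbol in the reference name table. That table often gives upper-case symbols of the human type, and 842 symbols are shared by 2 or more tested genes. Of 826 list entries, 256 matched a symbol exactly, 254 in another case and 172 after the paralogue letter was dropped, and 144 matched none. Where several genes carried a matched symbol, all of them entered the list. This matching rule was set after a first look at the genes with the smallest p, and exact matches alone were run as an alternative. Gene coordinates were not used.

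Genes were filtered with filterByExpr, which kept 19420 (15655 with a symbol), and scaled by TMM. The comparison of Amh with control used edgeR 4.0.16 (quasi-likelihood F test, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjusted p and a threshold of 0.05. A standard error is the size of the log2 fold change divided by the square root of F. Levels are CPM, counts scaled to library size, with TMM factors, and log2 levels use a prior count of 2. The 29 gene lists (18 of pathways and testis cells and 11 of other cell types and tissue state) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 29 lists, beside camera with an estimated correlation and fry. Members were also counted with p adjusted over the list alone, which makes no correction across lists. The test, the lists, the rule for named genes and the alternatives given as chosen in advance were set before the data were examined.

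The rule for named genes took 10 genes chosen for the question (igf3, insl3, amh, gsdf, star, cyp17a1, nanos2, dazl, id1 and sycp3), up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold with an average log2 CPM of at least 1, and the members with the smallest p of each list (2 in the 18 lists, 1 in the 11). No gene passed the unpaired test, so the part on the largest changes named none. Genes outside the rule are said to be named after their values were seen.

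Labels number the libraries 1 to 5 in each group without saying whether a number marks an animal. Deviations from the group mean correlated at 0.490 to 0.784 across genes between libraries of 1 number and at -0.338 to 0.130 between other libraries of the 2 groups, and 10 of 10 libraries correlated best with their own number. Genes are not independent replicates in these correlations. No 2 libraries were copies of 1 another beyond counting error (chi-square per degree of freedom 4.57 to 10.9 within numbers and 19.0 to 67.3 within groups). The biological coefficient of variation was 31.7% without and 11.9% with the replicate block. The numbers were therefore taken to pair the samples, by a rule fixed in advance, and the blocked comparison is given wherever it changed a call. Both fits had been printed before that rule was applied. Whether a number is an animal, a culture or a preparation is not stated, so p-values of single genes measure the spread between libraries as deposited. Camera's p-values compare a list's members with the other genes and rest on the preset correlation of 0.01. Among the lists that passed in the blocked comparison the estimated correlation was 0.0243 (Sertoli cell) to 0.424 (spermiogenesis). Their preset p-values therefore do not measure agreement between the pairs.

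Library totals were 8455226 to 15448069 counts, with 24403 to 26239 genes that had a read. A count of 3 is the upper limit that a count of 0 allows, 0.194 to 0.355 CPM by library. On data simulated once with the same depth and gene-wise dispersion (19420 genes, 200 changed), unpaired edgeR recovered 0%, 26.9% and 68.2% of log2 changes of 0.5, 1 and 2. The paired fit recovered 55.2%, 91.0% and 100% of them, with 23 false calls among 196 (0 among 63 unpaired). With no change simulated both made 0 calls, as did DESeq2 and limma-voom with and without the block. Genes were drawn independently, with 1 dispersion per gene for all pairs. The simulation therefore lacks correlation between genes and the wider spread of the number 2 pair, and rates in the real data may differ.

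Alternatives chosen in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter, at least 1 CPM in 5 libraries, the replicate block, library size as a covariate with and without the block, thinning to the smallest library, and leaving out each library in turn. Exact symbol matching, and the same alternatives with the replicate block (leaving out both libraries of a number), were chosen after seeing the data. In DESeq2 with the block 6401 genes had no adjusted p. A correction for GC content and gene length was not run, since it needs a genome sequence, which was not used here. No columns of another series were present, and every library was used. Some results for single genes are not reported here.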

Results

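RNA was sequenced from testis tissue of adult wild-type zebrafish after 3 days in culture with 11KT, the main androgen of male fish. In 5 libraries the tissue received 11KT alone (control), and in 5 it also received Amh, anti-Müllerian hormone, a ligand of the TGF-beta family that Sertoli cells make. Control libraries held 8455226 to 11934679 counts (n = 5) and Amh libraries 10974579 to 15448069 counts (n = 5). In each of the 5 replicate numbers that both groups share, the Amh library was 1.2 to 1.3 times as deep as the control library. A count of 3 stood for 0.194 to 0.355 CPM (counts scaled to library size), depending on the library. Such floors cover counting error only. Mitochondrially encoded transcripts took 5.92% ± 1.94 of counts in control libraries and 6.0% ± 2.45 in Amh libraries (SD, n = 5 each).

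Libraries lay closer to the library of the same number in the other group than to libraries of their own group. The first 4 principal components of log2 CPM held 26.7%, 24.6%, 17.1% and 12.0% of the variance, and 98.2% to 98.4% of each followed the replicate number. The group accounted for 0.0533% to 1.31% of these components and for 18.5% of the fifth, which held 6.92% of the variance. Values are therefore given for the unpaired comparison, the test set in advance, and also for the paired comparison, with the replicate number as a block, wherever it changed a call.

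**Figure D1:**
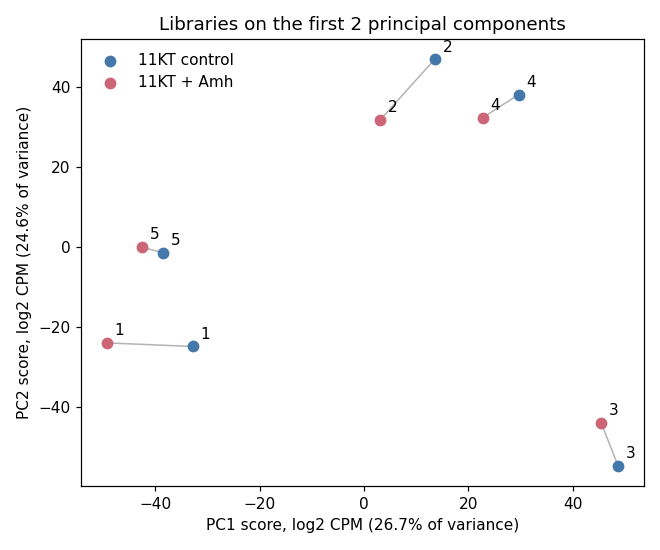
Principal components 1 (26.7% of variance) and 2 (24.6%) of log2 CPM for the 10 libraries, with colour for the group and a line joining libraries of 1 number. The libraries fall by number, not by group.

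The comparison of Amh with control asks how Amh acts on the testis beside 11KT, in a study that sets Amh against Igf3 in spermatogonial differentiation. When libraries were paired by number, 4 genes passed the test. On simulated data this paired fit made 23 false calls among 196, a larger share than the threshold of 0.05. cd74a (ENSDARG00000009087), the invariant chain that accompanies MHC class II, fell by 0.62 ± 0.083 on the log2 scale (SE, n = 5 pairs) and was lower in 5 of 5 pairs. The MHC class II gene mhc2dab (ENSDARG00000079105) fell by 0.78 ± 0.116 (SE), also in 5 of 5 pairs. ctsla (ENSDARG00000007836), a lysosomal cathepsin L, rose by 0.48 ± 0.0723 and tinagl1 (ENSDARG00000061231), a secreted matrix protein, by 0.59 ± 0.0935 (log2, SE), each in 5 of 5 pairs. In the unpaired comparison no gene passed.

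The mean level of cd74a was 95.9 ± 40.3 CPM in control and 62.0 ± 23.1 CPM in Amh libraries (SD, n = 5 each), and that of mhc2dab 32.6 ± 21.5 and 19.9 ± 14.3 CPM. ctsla stood at 574 ± 140 and 794 ± 161 CPM and tinagl1 at 39.0 ± 12.3 and 59.8 ± 22.4 CPM (SD, n = 5 each). Paired edgeR quasi-likelihood tests gave Benjamini-Hochberg adjusted p = 0.0296 for cd74a, 0.0414 for mhc2dab and ctsla, and 0.0484 for tinagl1. Unpaired, the log2 fold changes were -0.63 ± 0.293, -0.71 ± 0.750, 0.47 ± 0.195 and 0.62 ± 0.291 for cd74a, mhc2dab, ctsla and tinagl1 (SE), each with adjusted p = 0.9999. cd74a is named by the rule set in advance; mhc2dab, ctsla and tinagl1 were named after their values were seen. mhc2daa, another MHC class II gene named in the same way, had a paired log2 fold change of -0.63 ± 0.108 (SE, lower in 5 of 5 pairs), with adjusted p = 0.0700 in edgeR, 0.00394 in DESeq2 and 0.0497 in limma-voom.

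Of 19420 genes, unpaired edgeR called 0 (131 at an unadjusted p under 0.05, where 971 would come by chance), DESeq2 0 (162) and limma-voom 0 (136). Counts this far below chance mark the unpaired test as conservative, since it treats the spread between replicate numbers as noise. The biological coefficient of variation was 31.7% without and 11.9% with the block. The 0 unpaired calls are therefore weak evidence of no change. Paired edgeR called 4 (2 higher and 2 lower, 1694 at an unadjusted p under 0.05), DESeq2 25 (17 higher and 8 lower) and limma-voom 8 (5 higher and 3 lower), and 4 genes were shared by all 3 tools. With RLE or upper-quartile scaling the paired count was 3 (1 higher, 2 lower), with no low-count filter 113, and with library size as a further covariate 0 (799 at an unadjusted p under 0.05). Without the number 2 pair 229 genes passed (125 higher and 104 lower), without number 1 or number 3 a single gene did (0 and 1 of the 4), and without number 4 or number 5 none did (1439 and 1221 at an unadjusted p under 0.05, paired edgeR). Over these and the other alternatives cd74a passed in 9 of 13 (adjusted p = 5.8e-07 to 0.977), mhc2dab and ctsla in 8 each and tinagl1 in 5.

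**Figure D2:**
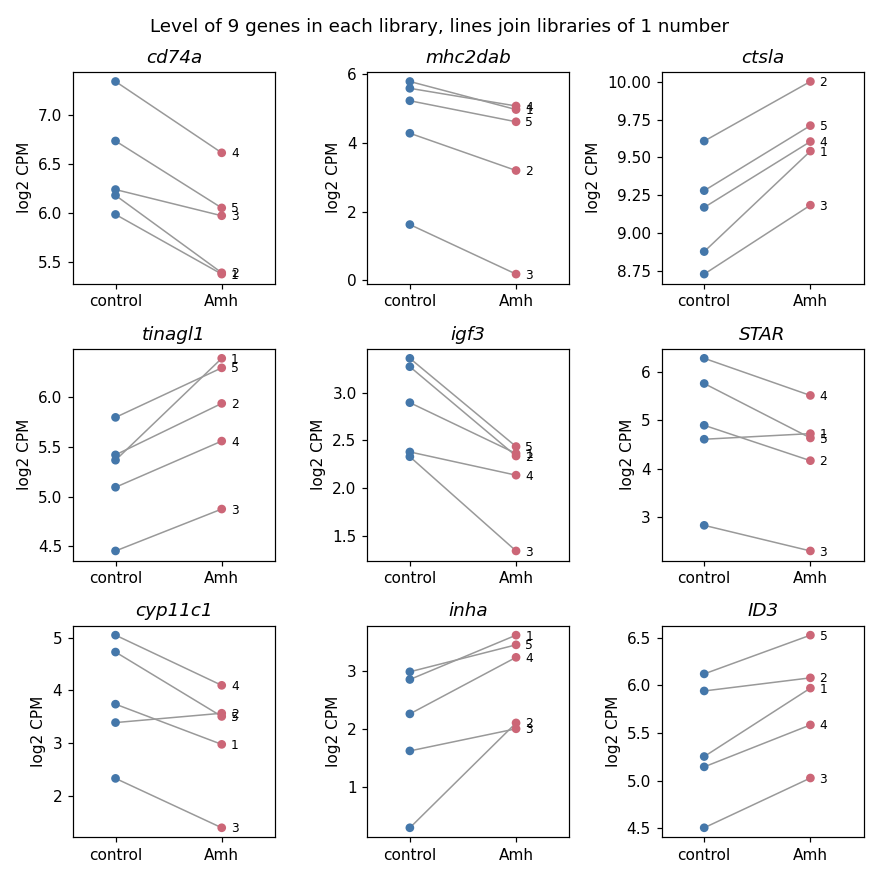
Level (log2 CPM) of cd74a, mhc2dab, ctsla, tinagl1, igf3, STAR, cyp11c1, inha and ID3 in each control and Amh library, with a line joining libraries of 1 number. cd74a, mhc2dab and igf3 are lower with Amh in 5 of 5 pairs, and ctsla, tinagl1, inha and ID3 are higher in 5 of 5.

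Genes of Leydig cells, which make androgens and Insl3, were lower with Amh in the paired comparison as a list of 20 (median log2 fold change -0.09, mean ratio below 0 in 3 of 5 pairs, camera adjusted p = 0.0105, and 0.540 with an estimated correlation). Adjusted over the list alone, 3 members fell and 0 rose, and 17 did not pass. STAR, which brings cholesterol into mitochondria, fell by 0.64 ± 0.14 and cyp11c1, an enzyme of the last steps to 11KT, by 0.77 ± 0.171 (log2, SE, list-alone adjusted p = 0.00359 for both). Each of them was lower in 4 of 5 pairs. HSD11B2, an enzyme that oxidises 11-hydroxysteroids, fell by 0.55 ± 0.128 (list-alone adjusted p = 0.00413, lower in 5 of 5 pairs). Over all genes 0 members passed in edgeR, unpaired or paired, while paired DESeq2 called STAR (adjusted p = 0.0404) and cyp11c1 (0.0466). CYP17A1, an enzyme of androgen synthesis, had an unpaired log2 fold change of -0.37 ± 0.258 (SE; 13.6 and 10.5 CPM), and insl3 one of -0.28 ± 0.655 (SE; 100.4 ± 68.9 and 82.4 ± 48.1 CPM, SD, n = 5 each). In the libraries numbered 3, insl3 stood at 11.7 CPM (control) and 8.48 CPM (Amh), against 75.3 CPM or more in the other 8 libraries.

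Unpaired, the median of the Leydig list was -0.07 and its adjusted p = 0.278 (0.00154 to 0.998 over its 21 alternatives). The unpaired list passed without control 3 (adjusted p = 0.00154, and 0.375 with an estimated correlation), and the paired list did not pass without number 4 (0.110), without number 5 (0.210), with no low-count filter (0.0761), with exact symbols alone (0.0507) or with library size as a covariate (0.191, median 1.03, direction up). The paired median was -0.13 without number 2, -0.19 without number 3 and -0.06 without number 5.

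Genes of Sertoli cells, the somatic cells that nurse germ cells, were higher with Amh in the paired comparison as a list of 21 (median log2 fold change 0.26, mean ratio above 0 in 5 of 5 pairs, camera adjusted p = 0.00326, and 0.493 with an estimated correlation). In pair 2 that mean ratio was 0.0021. Adjusted over the list alone, 4 members rose and 1 fell, and 16 did not pass. inha, the inhibin alpha subunit, rose by 0.82 ± 0.196 (log2, SE, list-alone adjusted p = 0.00534) from 4.69 ± 2.82 to 8.06 ± 3.85 CPM (SD, n = 5 each), in 5 of 5 pairs. CLU, the secreted chaperone clusterin, rose by 0.43 ± 0.0902 (0.00482, in 5 of 5 pairs). Over all genes CLU passed in paired DESeq2 (adjusted p = 0.0268) but not in paired edgeR (0.223) or limma-voom (0.132). gsdf, gonadal soma derived factor, rose by 0.33 ± 0.0934 and the tight-junction gene CLDN11 (ENSDARG00000020031, named after its values were seen) by 0.28 ± 0.0829, each in 4 of 5 pairs (list-alone adjusted p = 0.0152). igf3 (ENSDARG00000058058), a growth factor of the fish gonad, fell by 0.75 ± 0.18 (list-alone adjusted p = 0.00534) from 7.34 ± 2.44 to 4.33 ± 1.16 CPM (SD, n = 5 each), in 5 of 5 pairs. Over all genes igf3 did not pass in edgeR (unpaired log2 fold change -0.76 ± 0.29, adjusted p = 0.9999; paired adjusted p = 0.290). The gene of Amh itself, amh, had an unpaired log2 fold change of 0.22 ± 0.207 (SE, 90.6 and 105 CPM).

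Unpaired, the median of the Sertoli list was 0.22 and its adjusted p = 0.0698 (0.00326 to 0.952 over its 21 alternatives). It passed unpaired without Amh 2 (adjusted p = 0.00662), Amh 3 (0.0116), control 1 (0.0292) or control 4 (0.0413) and after thinning to 1 depth (0.0198), with 0.367 to 0.621 at an estimated correlation in these 5, and did not pass in the paired comparison with exact symbols alone (0.143) or with library size as a covariate (0.486, median 0.46). The paired median was 0.15 without number 1 or number 4.

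Of the lists of germ cell genes, 3 were shifted downward with Amh in camera's test at its preset correlation. The list of spermatogonial differentiation (10 genes, 3 of them also in the meiotic list and 2 in that of S phase) had a median log2 fold change of -0.12, with 9 of 10 members below 0 (camera adjusted p = 0.0156). That of meiotic prophase (29 genes) had a median of -0.12, with 25 of 29 members below 0 (camera adjusted p = 0.0156). The list of spermiogenesis and flagellum (33 genes) had a median of -0.13, with 31 of 33 members below 0 (camera adjusted p = 0.00285). No member of these 3 lists passed, over all genes or adjusted over the list alone, in either comparison. Over all genes edgeR, DESeq2 and limma-voom called 0 unpaired, and 0 of these members had an unadjusted p under 0.05 in unpaired edgeR (1, 5 and 6 members of the 3 lists in paired edgeR). With an estimated correlation the 3 lists gave adjusted p = 0.560, 0.560 and 0.60.

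KIT, the receptor whose signal accompanies spermatogonial differentiation, had an unpaired log2 fold change of -0.44 ± 0.211 and DAZL, a germ cell RNA-binding protein, one of -0.17 ± 0.111 (SE, n = 5 per group). Among meiotic genes terb2, which ties telomeres to the nuclear envelope, stood at -0.20 ± 0.138, SYCP3 of the synaptonemal complex at -0.09 ± 0.25, and prdm9, a meiotic histone methyltransferase, at 0.26 ± 0.166. The sperm flagellum genes ROPN1L and RSPH9 stood at -0.19 ± 0.113 and -0.16 ± 0.148. Undifferentiated spermatogonia (24 genes) had a median of 0.02 (adjusted p = 0.436), with etv5b, a transcription factor of spermatogonial stem cells, at 0.29 ± 0.182 and NANOS3 at 0.49 ± 0.354. Paired, etv5b stood at 0.29 ± 0.103 (higher in 5 of 5 pairs) and NANOS3 at 0.50 ± 0.353 (4 of 5). nanos2 had no tested gene under its symbol. Genes of S phase and mitosis (39 genes) had a median of -0.04 (adjusted p = 0.369), with CCND2 at -0.42 ± 0.283 and ORC1 at 0.25 ± 0.188.

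The paired comparison called the same 3 germ cell lists (adjusted p = 0.0307, 0.000822 and 7.8e-06 for spermatogonial differentiation, meiotic prophase and spermiogenesis, and 0.540 each with an estimated correlation). Their mean ratios were below 0 in 4, 3 and 4 of 5 pairs. Unpaired, the spermiogenesis call ended without Amh 5 (adjusted p = 0.233, median -0.08) or control 3 (0.832, median -0.01), with a range of 7.8e-06 to 0.952 over its 21 alternatives. Without control 2 or Amh 3 its median was -0.19 and -0.24, and -0.08 without number 1 in the paired comparison. The meiotic call ended without control 2 (0.103), control 4 (0.279), control 5 (0.0719), Amh 1 (0.110) or Amh 5 (0.233), with a range of 0.000822 to 0.959. The call of spermatogonial differentiation ended without control 2 (0.329), control 4 (0.173, median -0.08), control 5 (0.0530), Amh 1 (0.0647) or Amh 5 (0.120, median -0.07), with a range of 0.00392 to 0.952. Its median was -0.20 without control 3, -0.19 without Amh 3, -0.18 without Amh 4 and, paired, -0.20 without number 3. Paired, spermatogonial differentiation did not pass without number 2 (0.281), number 4 (0.106) or number 5 (0.191), nor meiotic prophase without number 5 (0.101) or with library size as a covariate (0.279, median 0.25, direction up), and S phase passed without number 2 (0.0347, and 0.582 with an estimated correlation) and, unpaired, without Amh 3 (0.0482, and 0.569). With the block and library size as a covariate, spermatogonial differentiation passed in the other direction, upward (camera adjusted p = 0.0104, median 1.07). Depth and group nearly coincide within pairs in that fit, so its direction is poorly determined. No list passed there with an estimated correlation.

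Macrophage and leukocyte genes (22 genes) were lower with Amh, with an unpaired median log2 fold change of -0.20 and 16 of 22 members below 0 (camera adjusted p = 0.00191, and 0.560 with an estimated correlation). In the paired comparison the median was -0.30 (mean ratio below 0 in 4 of 5 pairs, camera adjusted p = 6.2e-06, and 0.493 with an estimated correlation). Over all genes 2 members fell in the paired comparison (edgeR, DESeq2 and limma-voom), cd74a and mhc2dab, and 0 in the unpaired. Adjusted over the list alone, 8 fell, 1 rose and 13 did not pass in the paired comparison. Among those that fell were c1qa, a complement subunit, by 0.83 ± 0.293, ptprc, the pan-leukocyte phosphatase CD45, by 0.56 ± 0.187, and marco, a scavenger receptor, by 0.99 ± 0.367 (log2, SE, list-alone adjusted p = 0.0327, 0.0261 and 0.0381). They were lower in 5, 5 and 4 of 5 pairs. The cathepsin gene ctss2.1 rose by 0.41 ± 0.121 (list-alone adjusted p = 0.0191, higher in 4 of 5 pairs). c1qa, ptprc, marco and ctss2.1 were named after their values were seen. The unpaired call ended without Amh 5 (adjusted p = 0.0571, range 6.2e-06 to 0.162 over its 21 alternatives). With the block and library size as a covariate the list passed in the other direction, upward (camera adjusted p = 0.0490, median 1.14). Depth and group nearly coincide within pairs in that fit, whose median standard error rose from 0.133 to 1.07. Its direction is therefore poorly determined, and 0 lists passed there with an estimated correlation. The unpaired median was -0.12 without control 4, -0.30 without control 2, -0.41 without Amh 3 and -0.31 without Amh 4, and the paired median -0.18 without number 5.

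Erythrocyte genes (8 genes) were lower with Amh in the paired comparison (median -0.26, adjusted p = 0.0122, and 0.540 with an estimated correlation) and did not pass unpaired (median -0.27, adjusted p = 0.318). Adjusted over the list alone, the red-cell carbonic anhydrase cahz (named after its values were seen) fell by 0.49 ± 0.105 and the alpha globin hbaa2 by 0.30 ± 0.0975 (log2, SE, paired, adjusted p = 0.00212 and 0.0276), each in 5 of 5 pairs, and 6 members did not pass. Over all genes paired DESeq2 called cahz (0.0347), while paired edgeR (0.224) and limma-voom (0.208) did not. Without number 5 (0.192) or with library size as a covariate (0.652, median 0.30, direction up) the list did not pass (range 0.00658 to 0.652 over its 14 paired alternatives). Genes of immediate early response and heat shock (35 genes), a sign of handling and stress, were higher with Amh (unpaired median 0.11, 26 of 35 members above 0, adjusted p = 0.00191, and 0.560 with an estimated correlation), with a mean ratio above 0 in 5 of 5 pairs. The mitochondrial chaperone HSPD1, at 189 ± 27.8 and 228 ± 33.9 CPM (SD, n = 5 each), rose by 0.27 ± 0.0697 (log2, SE, paired, 0.0479 adjusted over the list alone), in 5 of 5 pairs. That list did not pass without Amh 5 (0.0571, median 0.08) or control 3 (0.207), with a range of 2.4e-05 to 0.952 over 21 alternatives, nor, paired, with library size as a covariate (0.907). Its median was 0.07 without control 4 or Amh 1 and 0.18 without Amh 3.

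**Figure D3:**
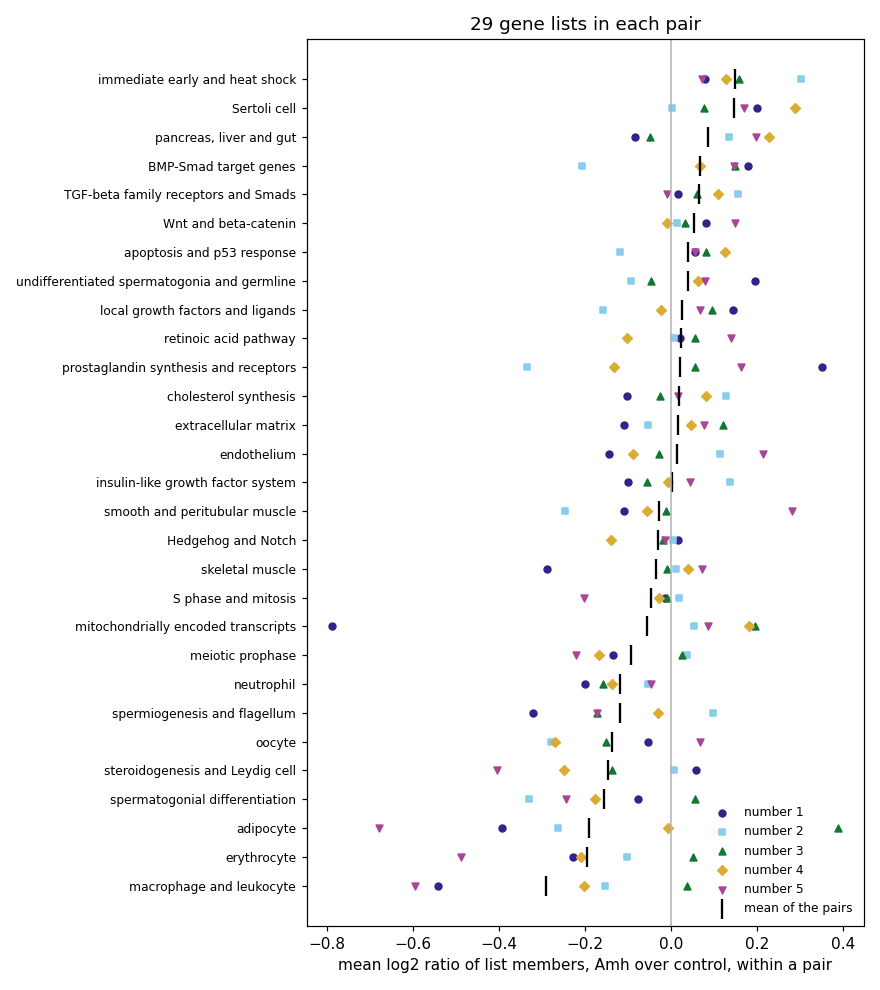
Mean log2 ratio of Amh to control over the members of each of the 29 lists, as 1 point per pair (n = 5) and a bar at their mean. The macrophage and leukocyte list lies lowest (mean -0.29), and the immediate early and Sertoli lists highest (0.15 each).

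Lists of signalling pathways did not pass camera in the unpaired or the paired comparison, while single members passed in the latter, adjusted over the list alone. Over all genes ID3 (adjusted p = 0.0309), PTGS2 (0.0304) and TIMP2 (0.00443) passed in paired DESeq2. ID3, PTGS2 and TIMP2 did not pass over all genes in paired edgeR (0.1905, 0.1948 and 0.1948) or paired limma-voom (0.1317, 0.0952 and 0.0952). Local growth factors and ligands (24 genes, 8 of them also in the Sertoli list) had a median log2 fold change of 0.06 (adjusted p = 0.622), and inha and gsdf rose while igf3 fell. TGF-beta family receptors and Smads (21 genes) had a median of 0.01 (0.369) and 0 members past the test (0 at an unadjusted p under 0.05 unpaired and 2 paired, edgeR). SMAD1 stood at 0.38 ± 0.234 and SMAD3 at 0.34 ± 0.218 unpaired (SE). In the paired comparison SMAD1 stood at 0.36 ± 0.0987 (higher in 5 of 5 pairs) and SMAD3 at 0.34 ± 0.183 (3 of 5). BMP-Smad target genes (23 genes) had a median of 0.07 (0.318). Among them ID3, an inhibitor of differentiation induced by BMP signals, rose by 0.44 ± 0.0876 (log2, SE, paired, 0.00271 adjusted over the list alone, in 5 of 5 pairs), while ID1 and msx1b stood at 0.15 ± 0.249 and 0.17 ± 0.119 unpaired. Without number 2 the BMP target list passed in the paired comparison (adjusted p = 0.00764, and 0.412 with an estimated correlation, range 0.00764 to 0.561 over its 14 paired alternatives).

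The insulin-like growth factor system (17 genes) had a median of 0.03 and a mean of -0.03 (adjusted p = 0.928, direction of the test up). In it IGFBP5, an IGF-binding protein, rose by 0.33 ± 0.0873 in the paired comparison (log2, SE, 0.0157 adjusted over the list alone, in 5 of 5 pairs), and igf3 fell (0.0130). Wnt and beta-catenin genes (27 genes) had a median of 0.05 (0.436). There the secreted Wnt modulator DKK3 rose by 0.38 ± 0.102 (paired, 0.0487 adjusted over the list alone, in 5 of 5 pairs), and the receptor FZD2 stood at 0.33 ± 0.252 unpaired. Prostaglandin synthesis and receptors (17 genes) had a median of 0.10 (0.622). PTGS2, the inducible cyclooxygenase, rose by 0.68 ± 0.139 (paired, 0.00290 adjusted over the list alone) in 5 of 5 pairs, and the receptor gene PTGER2 stood at 1.90 ± 0.950 and 0.778 ± 0.631 CPM.

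Extracellular matrix genes (36 genes) had a median of -0.01, a mean of 0.0016 and a test direction up (adjusted p = 0.874). TIMP2, an inhibitor of matrix metalloproteinases, rose by 0.41 ± 0.0839 in 5 of 5 pairs and the protease MMP14 by 0.32 ± 0.0858 in 4 of 5 (log2, SE, paired, adjusted over the list alone 0.00599 and 0.0334). Hedgehog and Notch genes (24 genes) had a median of -0.05 (0.749), with GLI2 at -0.26 ± 0.192 and LFNG at -0.39 ± 0.329. These values, and those that follow in this paragraph, are unpaired unless marked. The retinoic acid pathway (24 genes) had a median of 0.06 (0.749), with ALDH1A3 at -0.30 ± 0.212 and rxrgb at 0.31 ± 0.233. Cholesterol synthesis (21 genes) had a median of -0.05 (0.996), with SQLE at 0.42 ± 0.329 and LSS at -0.19 ± 0.182. Paired, SQLE stood at 0.42 ± 0.123 (higher in 5 of 5 pairs) and LSS at -0.19 ± 0.0766 (lower in 5 of 5). Apoptosis and p53 response (24 genes) had a median of 0.04 (0.436), with bida at -0.19 ± 0.137 and cdkn1a at 0.29 ± 0.208. No member of these last 4 lists passed in either comparison, over all genes or adjusted over the list alone (edgeR; 0 at an unadjusted p under 0.05 unpaired and 2, 1, 3 and 4 paired).

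Among markers of other cell types, endothelium (15 genes) had a median of 0.03 (adjusted p = 0.990). In it the receptor gene TIE1 fell by 1.17 ± 0.311 in the paired comparison (log2, SE, 0.0258 adjusted over the list alone) from 2.23 ± 1.23 to 0.953 ± 0.373 CPM (SD, n = 5 each), in 5 of 5 pairs. Neutrophil genes (7 genes) had a median of -0.11 (0.436), with lyz at -0.45 ± 0.276 (SE, unpaired, as for the genes in the rest of this paragraph). Smooth and peritubular muscle (17 genes) had a median of 0.04, a mean of -0.04 and a test direction down (0.996; up in the paired comparison), with MYL9 at 0.26 ± 0.159. Skeletal muscle (20 genes) had a median of -0.04 (0.781), with pvalb1 at -0.74 ± 0.419. Pancreas, liver and gut (14 genes) had a median and a mean of 0.05 and a test direction down (0.996; up in the paired comparison), with vtg1 at -0.51 ± 0.283. Adipocyte genes (7 genes) had a median of -0.05 (0.106), with DGAT2 at -0.45 ± 0.198, and passed without Amh 2 (0.0335), control 4 (0.0348) or, paired, number 3 (0.0113), with 0.367, 0.621 and 0.441 at an estimated correlation. Oocyte genes (10 genes) had a median of -0.17 (0.241), with ZAR1L at -0.18 ± 0.164, and passed without Amh 2 (0.0335, and 0.367 at an estimated correlation). Over their alternatives the 2 lists had adjusted p of 0.0335 to 0.994 (adipocyte) and 0.0335 to 0.952 (oocyte), unpaired.

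Mitochondrially encoded transcripts (13 genes) had an unpaired median and mean of 0.04 and 0.03 and a test direction down (adjusted p = 0.913), with MT-ND1 at 0.07 ± 0.342. Their mean log2 ratio was -0.79 in pair 1 and 0.05 to 0.19 in the other 4 pairs. The list passed upward without Amh 1 (adjusted p = 0.00188, and 0.696 with an estimated correlation) and downward without Amh 4 (0.00122, and 0.675), with a range of 0.00122 to 0.963 over 20 alternatives, and upward in the paired comparison without number 1 (7.3e-05, and 0.549).

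Of the 29 lists, 5 passed in the unpaired comparison (1 up, 4 down) and 8 in the paired (2 up, 6 down). With an estimated correlation 0 did in either (camera, 1 and 2 at an unadjusted p under 0.05), and fry, which asks whether members move on balance in 1 direction, called 0 in either (1 and 5 at an unadjusted p under 0.05). fry's test for change in either direction called 0 lists unpaired and 5 paired: Sertoli cell (adjusted p = 0.000254), growth factors (0.0318), the insulin-like growth factor system (0.00055), apoptosis (0.0171) and macrophage and leukocyte (0.0228). The unpaired count went from 5 to 0 without Amh 5 (6 at an unadjusted p under 0.05), to 8 without Amh 2, to 3 without control 2 or control 5, to 3 with no low-count filter, to 1 with exact symbols alone and to 0 with library size as a covariate (2 at an unadjusted p under 0.05). With exact symbols alone the meiotic, spermiogenesis and immediate early lists did not pass (adjusted p = 0.239 each) and spermatogonial differentiation had too few members for the test. With no low-count filter spermatogonial differentiation and meiotic prophase did not pass (0.0666 each), and with library size as a covariate none of the 5 did (0.162 to 0.959). The paired count went to 4 without number 5 and to 5 with exact symbols alone or with library size as a covariate. With the labels exchanged within pairs in other ways, the paired count was 1 to 8, with a median of 4. Of 576 different members, 0 passed unpaired in edgeR over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05 (83 in the paired comparison).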

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

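The tests of germ cell share, leukocyte number, sequencing depth, batch and exchanged labels in this part were all chosen after the results they address were seen.

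In camera's test at its preset correlation, the lists of spermatogonial differentiation, meiotic prophase and spermiogenesis were lower with Amh, unpaired and paired. The Sertoli cell list was higher in the paired comparison (adjusted p = 0.00326) and did not pass unpaired (0.0698). Undifferentiated spermatogonia were not lower as a list (median 0.02 unpaired and 0.03 paired). A lower share of germ cells as the whole cause would raise the markers of every other cell type alike. The macrophage and leukocyte median minus the Sertoli median was -0.56 (95% bootstrap interval over members -0.75 to -0.19, paired log2 fold change). Both lists were compared after the same paired fit had called them in opposite directions, so a difference below 0 was given in advance. The interval also covers genes, not pairs, so the difference cannot decide the question. Leydig (-0.34, -0.63 to -0.040) and erythrocyte medians (-0.51, -0.67 to -0.14) also lay below the Sertoli median, while the intervals for endothelium (-0.21, -0.33 to 0.099) and smooth muscle (-0.19, -0.43 to 0.081) included 0. A lower share of germ cells and a change in Sertoli cells themselves both stay open. After all libraries were thinned to 1 total, the spermiogenesis list still passed the paired test (adjusted p = 1.0e-05, and 0.557 with an estimated correlation, median -0.13). Its adjusted p ranged from 2.6e-10 to 0.0177 over its 14 paired alternatives, and its mean ratio was below 0 in 4 of 5 pairs. Unequal read numbers alone therefore did not make that call. Thinning leaves the expected fold changes as they were, so a library difference that goes with depth stays open. With library size as a covariate the list did not pass unpaired (camera adjusted p = 0.952) and passed with the block. A response to Amh, the difference that the design names, stays among the open explanations, and a library batch that follows the groups cannot be told apart from it because the labels give no batch.

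cd74a and the MHC class II gene mhc2dab were lower with Amh in the paired comparison, while mhc2daa (-0.63) and cd74b (-0.36) did not pass in edgeR (adjusted p = 0.0700 and 0.297), and unpaired none of the 4 did (0.9999 each). After thinning, cd74a still passed the paired test (adjusted p = 0.0102, range 5.8e-07 to 0.977 over its 13 alternatives, lower in 5 of 5 pairs), so unequal read numbers alone did not make that call. Thinning leaves the expected fold changes as they were, so a library difference that goes with depth stays open. With the block and library size as a covariate, cd74a stood at 0.75 and mhc2dab at -1.97 (log2, edgeR adjusted p = 0.977 for both). A library or sequencing batch that follows the groups cannot be told apart from Amh, since the Amh libraries were 1.2 to 1.3 times as deep as their controls and the labels give no batch. Fewer leukocytes stay open: the median of the 19 members of the macrophage and leukocyte list other than cd74a, cd74b and mhc2dab was -0.22 (interval -0.43 to 0.074, 13 of 19 below 0), with c1qa at -0.83, marco at -0.99 and ptprc at -0.56, against -0.63 for these 3 genes and mhc2daa, which were picked because they fell. A change within leukocytes, or of 1 kind of leukocyte, is a candidate explanation that was not tested.

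The number 2 pair stood apart from the other pairs. Shallower sequencing is argued against, since the spread over genes of its log2 ratios after thinning was an SD of 0.382 (interval 0.374 to 0.390, over 11962 genes with an average log2 CPM of at least 3), against at most 0.291 in the other pairs. Exchanged labels stay open, since 44% of the 100 genes with the smallest p in the other pairs had the same sign in pair 2, between the 61% or more of the other pairs and the 39% or less that exchanged labels would give, while cd74a (-0.79), mhc2dab (-1.09), ctsla (0.39) and tinagl1 (0.52), picked over all 5 pairs, went with the labels in pair 2, as did its depth ratio of 1.3. With the labels of pair 2 exchanged, 2234 genes had an unadjusted p under 0.05 (1694 as labelled), and edgeR called 1 gene (4 as labelled). A difference between the animals or tissues of the pairs stays open and was not tested.

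Of 212 groups of 5 values, 15 held a library far from the other 4, with a gap to the nearest library that was more than 0.71 of the group's whole range, where chance gives about 10.6. By library these were 4 in Amh 3, 3 each in Amh 5 and control 3, 2 each in Amh 2 and control 2, and 1 in Amh 4. Values in the sentences that follow are that share of the range and levels in log2 CPM.

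In Amh 3, insl3 was low (0.779; 3.11 against 6.24 to 7.13), as were igf3 (0.726; 1.34 against 2.13 to 2.43), hbaa2 (0.746; 3.20 against 4.44 to 4.87) and the mean of the Leydig cell list (0.789; 2.76 against 3.44 to 3.62). In control 3, CDH2 was low (0.839; 6.54 against 7.16 to 7.27), as were GLI2 (0.837; 3.33 against 3.84 to 3.94) and the mean of the growth factor list (0.716; 2.47 against 2.72 to 2.82). In Amh 5, TIMP2 was high (0.786; 10.33 against 9.29 to 9.51), as were HSPD1 (0.736; 8.17 against 7.70 to 7.82) and the mean of the cholesterol synthesis list (0.894; 4.56 against 4.30 to 4.33). In control 2, amh was high (0.738; 7.20 against 6.15 to 6.42), as was KIT (0.910; 3.60 against 2.91 to 2.97). In Amh 2, cd74b was low (0.732; 6.0 against 6.71 to 6.97) and ORC1 high (0.879; 4.77 against 4.19 to 4.26). In Amh 4, gsdf was high (0.793; 10.86 against 10.03 to 10.20).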

How the results depend on the processing

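Exact symbol matching and every alternative of the paired comparison except that with library size as a covariate were chosen after seeing the data. In the unpaired comparison 52 genes and 29 lists were followed, and in the paired comparison 41 genes and 8 lists. The unpaired count of 0 genes (edgeR, 131 at an unadjusted p under 0.05, and 0 in DESeq2 and limma-voom) was left at 0 by the alternatives run other than the replicate block. Direction changed 121 times unpaired, 4 of these with a value past the threshold before or after, and 18 times paired, 6 of these. Apart from the calls named beside the results, the replicate block changed no call. A list's direction here is that of camera's test, so a median can keep its sign. The correction for GC content and gene length was not run, since it needs a genome sequence, which was not used here. Depth limits genes near 0.194 to 0.355 CPM, and of simulated log2 changes of 1 unpaired edgeR recovered 26.9%, DESeq2 49.3% and limma-voom 28.4%. Where no cause is named for a change below, the cause was not tested.

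Smooth and peritubular muscle, which tested down at a median of 0.04, tested up with RLE scaling (median 0.042), upper-quartile scaling (0.041), DESeq2 (0.046), limma-voom (0.084), no low-count filter (0.056), the replicate block (0.069), library size as a covariate (0.12) and exact symbols (0.044). Mitochondrially encoded transcripts reversed with DESeq2 (0.037), and with limma-voom MT-ND1 (-0.020) and cholesterol synthesis (-0.025) did. With no low-count filter 3 lists passed, and the growth factor list (-0.0069) and cholesterol synthesis (-0.050) reversed. With at least 1 CPM in 5 libraries the insulin-like growth factor list reversed (0.013), and after thinning endothelium did (0.11). With exact symbols alone, which left fewer members per list, 1 list passed, and Wnt and beta-catenin (-0.050), Hedgehog and Notch (-0.027), the insulin-like growth factor list (-0.073) and adipocyte (0.0035) reversed. The replicate block gave 4 genes (2 higher and 2 lower) and 8 lists, and reversed MT-ND1 (-0.023) and pancreas, liver and gut (0.018).

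With library size as a covariate, unpaired, 0 lists passed (camera, 2 at an unadjusted p under 0.05). The genes SYCP3 (0.22), SMAD1 (-0.041), FZD2 (-0.0021), LSS (0.21), SQLE (-0.22), HSPD1 (-0.026), inha (-0.66) and terb2 (0.0092) reversed. So did the lists of Sertoli cell (-0.029), growth factors (0.093), BMP-Smad targets (-0.026), S phase and mitosis (0.051), Hedgehog and Notch (-0.018), apoptosis (-0.041), endothelium (-0.15), skeletal muscle (0.20), adipocyte (0.049), oocyte (0.30) and mitochondrially encoded transcripts (0.27).

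With the replicate block and library size together 0 genes passed (0 higher, 0 lower, 799 at an unadjusted p under 0.05 in edgeR) and 5 lists did. Depth and group nearly coincide within pairs (ratios of 1.2 to 1.3 in 5 of 5), so the median standard error rose from 0.133 to 1.07. Many estimates changed direction too, and which of these ended the calls was not tested. Reversed genes were CYP17A1 (1.06), STAR (1.84), SYCP3 (1.23), gsdf (-1.16), insl3 (1.47), DAZL (1.1), msx1b (-0.30), LFNG (2.43), CCND2 (1.36), SMAD3 (-0.94), DGAT2 (0.75), bida (0.18), HSPD1 (-0.081), inha (-0.82), cd74a (0.75), terb2 (0.12), MT-ND1 (-0.078), PTGER2 (3.91), PTGS2 (-0.67), ALDH1A3 (0.45), rxrgb (-0.27), HSD11B2 (2.03), NANOS3 (-0.73), CDC42EP3 (-0.18), CORO1A (0.50), aanat2 (-2.91), cd74b (1.27), grna (1.53) and marco (2.19). Reversed lists were Leydig cell (1.03), spermatogonial differentiation (1.07), meiotic prophase (0.25), S phase and mitosis (0.52), Hedgehog and Notch (-0.054), insulin-like growth factor (-0.32), erythrocyte (0.30), macrophage and leukocyte (1.14), neutrophil (-0.22), endothelium (-0.43), smooth and peritubular muscle (-0.13) and adipocyte (1.74). Of these, spermatogonial differentiation (adjusted p = 0.0104) and macrophage and leukocyte (0.0490) passed upward, in a range over all paired alternatives of 0.00212 to 0.281 and 7.2e-10 to 0.0490. With an estimated correlation 0 lists passed in this setting. BMP-Smad targets (0.0490) and extracellular matrix (0.0190) gained a call upward (0.754 each with an estimated correlation). Leydig cell (0.191), Sertoli cell (0.486), meiotic prophase (0.279), erythrocyte (0.652) and immediate early and heat shock (0.907) lost theirs.

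In the paired comparison RLE scaling, upper-quartile scaling and the filter of at least 1 CPM left 1 gene higher. DESeq2 called 25 genes (17 higher, 8 lower), limma-voom 8 (5 higher) and no low-count filter 113 (56 higher, 57 lower), where the prior degrees of freedom went from 11.9 to 147. Exact symbols left 5 lists.

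Leaving out 1 library at a time, the unpaired number of lists ranged from 0 (without Amh 5, 6 at an unadjusted camera p under 0.05) to 8 (without Amh 2). Ranges for values whose direction (for lists that of camera's test) or call changed were -0.22 to 0.28 for MT-ND1, -0.23 to 0.042 for SYCP3, -0.57 to 0.15 for insl3 and -0.045 to 0.33 for ID1. For list medians they were -0.022 to 0.083 for retinoic acid, -0.086 to 0.020 for cholesterol synthesis, -0.065 to 0.076 for smooth and peritubular muscle, -0.010 to 0.15 for endothelium, -0.27 to 0.26 for mitochondrially encoded transcripts, 0.022 to 0.13 for growth factors and -0.10 to 0.047 for extracellular matrix. They were -0.025 to 0.11 for apoptosis, -0.11 to 0.082 for skeletal muscle, -0.080 to 0.17 for pancreas, liver and gut, -0.0036 to 0.094 for the insulin-like growth factor list, -0.16 to -0.037 for Leydig cell and -0.14 to 0.021 for S phase and mitosis. Among lists whose call alone changed they were -0.24 to -0.0050 for spermiogenesis, -0.14 to -0.081 for meiotic prophase, -0.20 to -0.069 for spermatogonial differentiation, 0.13 to 0.27 for Sertoli cell, -0.41 to -0.12 for macrophage and leukocyte, 0.066 to 0.18 for immediate early and heat shock, -0.32 to -0.013 for adipocyte and -0.25 to -0.039 for oocyte. Leaving out 1 pair at a time, the paired comparison called 0 (without number 4 or 5) to 229 genes (without number 2), 0 to 125 higher and 0 to 104 lower, and 4 (without number 5) to 9 lists (without number 1, 2 or 3).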

Other observations

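The description of genes called without the number 2 pair and the tests on pairs left out and on unpaired splits for genes were chosen after those results were seen.

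Without the number 2 pair 229 genes passed in the paired comparison (edgeR, adjusted p under 0.05), and those described here were named after their values were seen. The matrix genes adamtsl7 and EFEMP2 had log2 fold changes of 0.64 ± 0.0933 and 0.57 ± 0.0834 (SE, n = 4 pairs), against 0.35 and 0.062 in pair 2. The steroidogenic genes cyp11c1 and hsd3b1 stood at -1.0 ± 0.13 and -0.62 ± 0.155, against 0.18 each in pair 2, and STAR and HSD11B2 at -0.62 ± 0.132 and -0.38 ± 0.0901, against -0.73 and -1.27 in pair 2. ID3 stood at 0.52 ± 0.0801, SMAD1 at 0.44 ± 0.0897 and amh at 0.40 ± 0.0866, against 0.14, 0.0047 and -0.32 in pair 2. The dynein genes dnah9l, DNAH10 and DNAH2, of motile cilia and flagella, stood at -0.44 ± 0.0833, -0.32 ± 0.0763 and -0.32 ± 0.0822, against -0.022, 0.54 and 0.58 in pair 2. Of the 228 called genes that were also tested in all pairs, 102 (44.7%) had the same sign in pair 2.

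CCN2, a target gene of the co-activators YAP and TAZ, was named after its values were seen. It had a paired log2 fold change of 0.42 ± 0.0803 (SE, edgeR adjusted p = 0.176, higher in 5 of 5 pairs). As a hypothesis, Amh may raise the activity of YAP and TAZ in this tissue. A list of 20 other known targets, written before it was tested and without CCN2 and AMOTL2, gave 16 tested genes for 13 entries, with a median log2 fold change of 0.17 (interval 0.088 to 0.29) and 13 of 16 above 0. Camera gave p = 0.0041 at the preset correlation and p = 0.0801 with an estimated correlation (1 list, so unadjusted), and 0 members passed an adjusted p of 0.05 in paired edgeR. The hypothesis stays open.

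In a test of whether all pairs share 1 response, the 100 genes with the smallest p in 4 pairs had the same sign in the pair left out in 80%, 44%, 61%, 78% and 80% of cases for pairs 1 to 5, a mean of 68.6%. Among the 16 ways of exchanging labels within pairs, 3 gave a mean as high, the highest 75.2%, with pair 2 exchanged, so a shared response stays open.

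The samples were also split in other ways. For genes in the unpaired comparison the real split called 0 (edgeR, 131 at an unadjusted p under 0.05, and 0 in DESeq2 and limma-voom), so 100 of 100 drawn splits had to call as many, which decides nothing about chance, and the highest other called 334. That number points to a structure of the samples, the replicate numbers, since that split parts 1 pair, while the real one parts all 5. For lists in the unpaired comparison the real split called 5, and 13 of 100 splits called as many, the highest other 7, so chance is not excluded. The 12 others that called as many part 1 to 3 pairs, and among the 12 other drawn splits that part all 5 pairs, as the real one does, the highest called 4 lists. Those 13 splits are too few for a share under 0.05. For the paired comparison the 16 splits that part all pairs are too few for a share under 0.05. The real split called 4 genes and the highest other 1, with 1 of 16 as high. It called 8 lists and the highest other 8, with 2 of 16 as high. The other splits within pairs called 1 to 8 lists, with a median of 4. Camera at its preset correlation thus called lists under exchanged labels too.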
